A study of Mus musculus with 18 samples.

How the data were processed

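Genomic DNA from mouse tails was measured by array comparative genomic hybridisation, in which DNA of a test animal and of a reference animal are labelled with different dyes and hybridised to the same array. There were 18 arrays of 9 C57BL/6 mice of 1 family: a father, a mother and 7 progeny, here called progeny 1 to progeny 7. Every mouse was compared with the same reference male mouse on 2 arrays with the dyes Cy5 and Cy3 exchanged, and the pair was counted as 1 replicate. Groups and animal numbers came from the labels.

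Per the file headers, the arrays were scanned at a resolution of 3 µm and read with Agilent Feature Extraction version 12.1.0.3. Per the labels, DNA was labelled by version 4.0.8 of the Agilent protocol for this assay. The deposited intensity values used here were the processed signals of each channel, which per the file headers had been background-subtracted with a spatial trend, corrected for a multiplicative trend and scaled by a linear dye normalization. The deposited intensity files also hold median spot and local background signals and quality marks given as 0 or 1. A deposited value table holds 1 log2 ratio per spot and array, and how the authors made it is not given in the sources used here. Compared spot by spot with the scanner values, these deposited log2 ratios ran as reference over mouse with absolute correlations between 0.984 and 1.0, absolute slopes between 0.966 and 1.0 and medians between -0.0093 and 0.0322. The table's direction and scale were thereby settled, and how it was centred remains unknown.

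Each array had 973116 spots, of which 6745 were controls and were left out. The other 966371 spots covered 950744 positions given on the mouse build mm9 (NCBI37), and log ratios of spots at the same position were averaged. The probes, with a median length of 60 bases, lay on the 19 autosomes at 950617 positions with a median spacing of 2053 bp, and only 68 lay on X, 23 on Y and 36 on unplaced contigs. The files hold no gene column. The gene table at hand follows another build and coordinates were not converted, so regions are given by position only and the planned comparison of gene lists was not run.

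The log2 ratio of mouse over reference was computed from the processed signals, with the direction taken from the dyes in the labels. Each array was centred on its autosomal median with no loess or quantile step, and the arrays of a pair were averaged. Arrays of 1 orientation from different mice correlated over all probes at r between -0.25 and 0.61 with the mouse in Cy5 and between 0.16 and 0.60 with the mouse in Cy3.

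Copy number intervals were searched on the autosomes of each mouse. Values were scaled by the mouse's own robust spread, the scaled median absolute deviation, and the interval of 3 to 2000 probes with the largest absolute sum divided by the square root of its probe number was taken, repeatedly, down to a score of 6. An interval was called when its mean log2 ratio was at least 0.25 in size and both dye orientations had a mean of the same sign and of at least that size. As a background, the search was repeated on tracks in which the array with the mouse in Cy3 was turned around, so that copy number cancels and array noise stays. The dye bias common to all mice was subtracted from these tracks, a step added after the data were seen. Effects of a DNA sample that do not depend on the dye cancel there too, so an excess over this background is not by itself a copy number difference.

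Calls of 1 direction were joined into a region when they overlapped by at least 50% of both in probes. A mouse carried a region when its mean there had the same sign in both orientations, a score of at least 3 and at least 50% of the median of the calling mice. Regions carried by all 9 mice were named shared, those carried by at least 1 parent but not by all mice segregating, and those carried by neither parent progeny-only. The difference between father and mother was searched in the same way. Inheritance was tested against 50% with an exact binomial test over pairs of region and progeny mouse, which are not independent, and with a permutation test over regions that flips each region's deviation from 50%, with 100000 draws or all flips. Chromosome medians were tested over the 7 progeny with a two-sided exact sign-flip permutation test. Single probes were tested with limma on the pair means, for the family against 0 and for progeny against parents, with Benjamini-Hochberg adjustment at 0.05. The only common reference was 1 mouse, so the test against 0 leaves out the spread between reference animals.

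The named regions were the 10 of largest absolute score among the segregating, the progeny-only and the father against mother regions, and all shared regions. Regions of at least 10 probes and those called in at least 3 mice were also named, and this was chosen after their values were seen. At most 2 probes per direction were named for limma. The design, the named regions and most alternatives were fixed before the data were examined: score limits of 5 and 8, at least 5 probes, mean ratios of 0.15 and 0.4, normexp background correction with an offset of 50, a running median subtracted along chromosomes, dim or marked spots left out, the deposited value table, single dye orientations, other carrier and linking rules, limma with trend and robust variance, an added size limit, scan day as a block and each progeny mouse left out. Because no mean signal column was at hand, normexp used the median signals. The 5 scan days held the parents on 1 day and the progeny on the other 4, so day was fitted as a random block in limma and could not be applied to calls made within 1 mouse.

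The interval search in single mice, the region classes and limma were tested on simulated data made from the real tracks. Planted intervals of 3 probes were called in 84.0% of cases at a log2 ratio of 0.6 and in 8.7% at 0.3. Planted intervals of 10 probes were called in 99.3% and 46.0% of cases. They were planted on the tracks without copy number, from which the dye bias common to all mice had been subtracted. The real tracks keep that bias and a call needs both orientations, so recovery in real data may be lower. For limma, 97.5% of probes planted at 0.5 were recovered in the family comparison, against 0% at 0.5 and 83.5% at 1 in the comparison of progeny with parents, each over 950617 probes. The family figure does not measure the recovery in real data. The mean over the 9 mice had been subtracted from the tracks used, so the family mean of each probe was 0 before planting. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.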

Results

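The series belongs to a study of DNA copy number in the offspring of male mice exposed to continuous low-dose-rate gamma-rays, and holds the primary screen of the family named for 0.05 mGy per day over 400 days. The screen asks whether progeny carry copy number aberrations that both parents lack. Tail DNA of 1 father, 1 mother and 7 progeny was compared with 1 reference male of the same colony. The labels conflict on the father: the title speaks of exposed males, whereas the opening of the design text lists this male as non-irradiated. With 1 animal per parent and 1 family, no comparison here tests irradiation. Later arrays and polymerase chain reaction assays named in the design text were not analysed here.

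Median spot signals in the mouse's channel lay between 85.0 and 269 units against local backgrounds of 22.0 to 32.0, and progeny 3 had the dimmest pair with 85.0 and 107. Between 0.0501% and 0.700% of spots per array were not well above background or marked as irregular, and 0 spots were saturated. The SD of ratios between neighbouring probes was 0.17 to 0.30 on 17 arrays and 0.43 on the array with progeny 2 in Cy5, which failed the scanner software's limit for this measure. The 2 arrays of a pair correlated over probes at r between -0.54 in progeny 2 and 0.07 in progeny 6, so for most single probes noise and dye bias exceeded any copy number signal. With the dye bias common to all mice subtracted, r lay between -0.23 in progeny 2 and 0.40 in progeny 6. The number of animals and arrays limits the precision of every value.

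Copy number calls were dominated by very short intervals, whereas long intervals were few, and 3 of the 5 regions of at least 10 probes were called in several mice. The search called 808 intervals in the 9 mice, 359 gains and 449 losses, from 6 in progeny 2 to 243 in progeny 3. Losses did not outnumber gains in every setting: there were 412 gains and 272 losses with the mouse in Cy5 only, and 306 and 259 without progeny 3. The father had 71 calls and the mother 132. Of all calls, 747 spanned 3 to 4 probes and 20 spanned at least 10 probes. The tracks without copy number gave 411 calls, 391 of them of 3 to 4 probes and 3 of at least 10. In progeny 6 the track without copy number gave 46 calls and the real track 19. Many short calls rested on 1 probe: without the strongest probe, a criterion chosen after the data were seen, the remaining probes averaged at least 0.25 in 37.1% of calls of 3 to 4 probes, against 30.4% on the tracks without copy number, and in 19 of the 20 calls of at least 10 probes. The count fell to 161 with normexp background correction and to 335 without dim or marked spots.

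**Figure D1:**
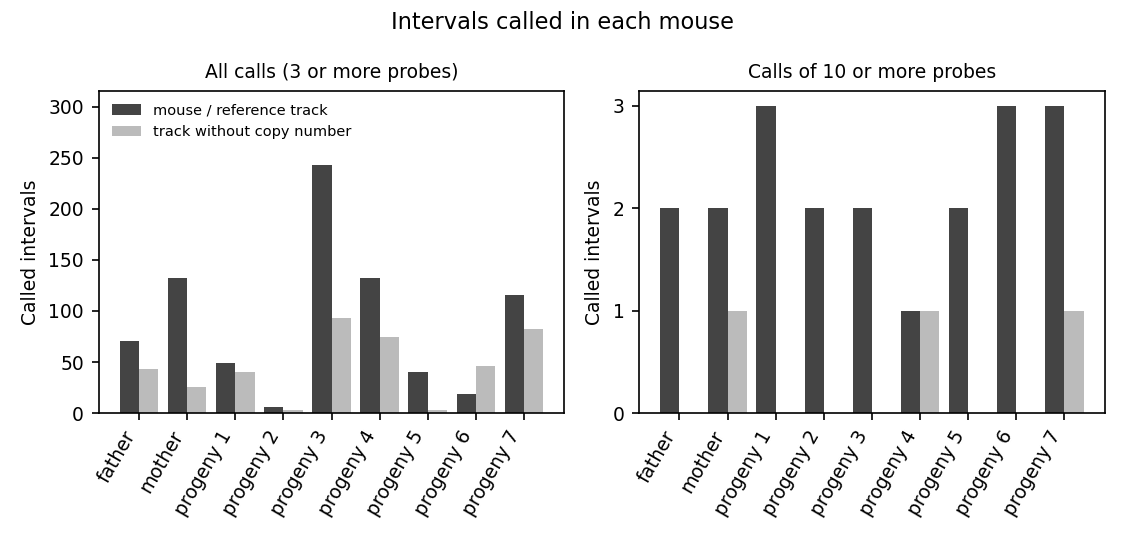
Bars give the number of called intervals per mouse on the track of mouse over reference (dark) and on the track in which copy number cancels (light), for all calls at left and for calls of at least 10 probes at right. All calls together range from 6 in progeny 2 to 243 in progeny 3, with 411 on the tracks without copy number, whereas the calls of at least 10 probes number 20 in all against 3 without copy number.

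All 9 mice shared 2 losses relative to the reference mouse, on chromosomes 10 and 14. The loss on chromosome 10, from 33897213 to 33933441 (mm9, 19 probes), was called in each of the 9 mice with the same first and last probe, at a mean log2 ratio of -0.56 ± 0.04 (SD, n = 9) and between -0.60 and -0.49 in single mice. The loss on chromosome 14, from 53430657 to 54181712 (79 probes), was shallower, at -0.29 ± 0.04 (SD, n = 9). It passed the call limits in the father and progeny 1, 6 and 7, and the other mice carried it. The track without copy number gives no background for shared regions. Its mean over the 9 mice was subtracted at each probe, so all mice could not deviate in the same direction there. Because every mouse was measured against 1 reference animal, a ratio alone does not name the side that differs in copy number. A loss of 1 of 2 copies in the mice would give -1 on this scale. All 9 mice lay well above that on chromosome 10, which argues against such a loss there. A reference with 3 copies against 2 in the mice would give a ratio below 0 by 0.58, near the value seen. For chromosome 14 the side stays open. The loss on chromosome 14 was no longer called over at least 10 probes with a mean ratio limit of 0.4 and was not carried by all mice with normexp.

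The depth of the chromosome 14 loss was uneven and its ends varied between mice. In bins of 100 kb the mean over 9 mice was -0.23 from 53400000, reached -0.48 from 53700000 and rose to -0.07 from 54000000. It fell again to -0.25 from 54100000, was -0.13 from 54300000, beyond the called end, and 0.0018 from 54400000. Calls in single mice began as early as 53414208 and ended as late as 54361298. Probes were sparse there, with 1 probe per 9.51 kb, against 1 per 1.91 kb in the loss on chromosome 10.

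**Figure D2:**
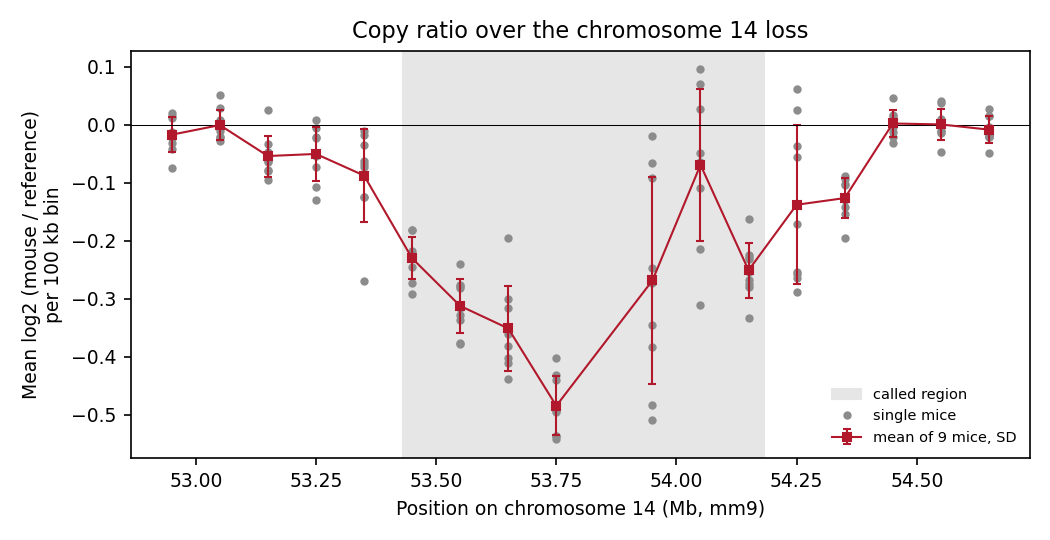
Points give the mean log2 ratio of mouse over reference per 100 kb bin on chromosome 14 for each of the 9 mice, squares and bars give their mean and SD, and shading marks the called region. The ratio falls in steps to -0.48 in the bin from 53700000, dips again to -0.25 in the bin from 54100000 and returns to about 0 from 54400000.

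Within the family, 1 long gain segregated. It lay on chromosome 4 from 101110482 to 101270535 (mm9, 74 probes) and was carried by the mother and by progeny 3, 5, 6 and 7, at a mean log2 ratio of 0.55 ± 0.01 (SD, n = 5), with single values between 0.53 and 0.57. The father and progeny 1, 2 and 4 had a mean of 0.01 ± 0.02 (SD, n = 4) there, with single values between -0.02 and 0.04, so the gap was far larger than the spread on either side. The calls had identical end probes in all 5 carriers. The adjacent probes outside the gain ended at 101107190 and began at 101274108. The track without copy number also gave 1 segregating region of at least 10 probes. Without the strongest probe, 0 of the 3 calls of that length on these tracks averaged at least 0.25. The gain averaged between 0.53 and 0.56 without it in the 5 carriers. A gain from 2 to 3 copies corresponds to 0.58 on this scale. The gain was found in 4 of 7 progeny (exact binomial p = 1.0 against 50%).

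**Figure D3:**
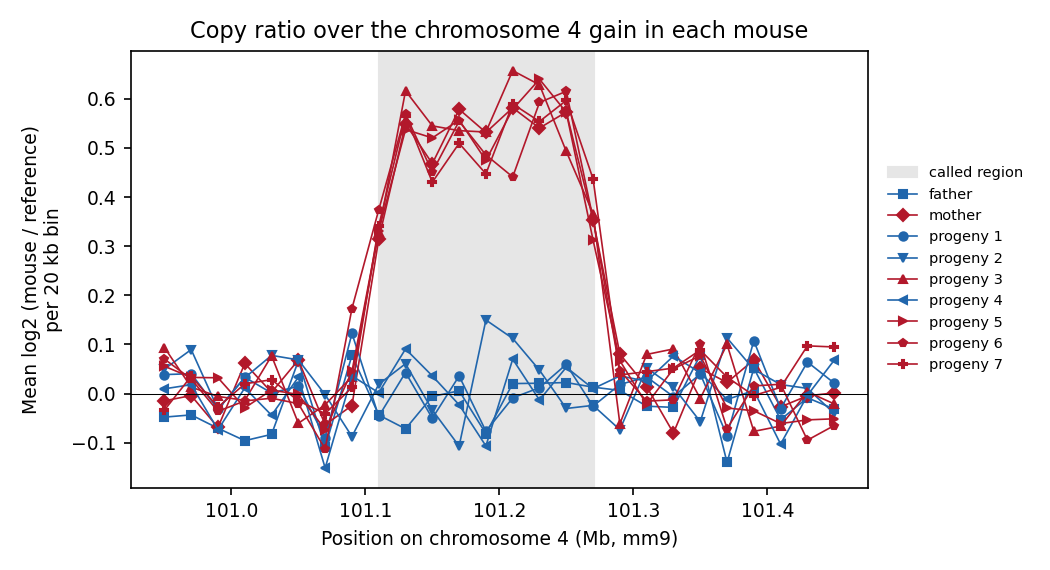
Lines give the mean log2 ratio of mouse over reference per 20 kb bin on chromosome 4 for each mouse, with carriers of the gain in red, other mice in blue and the called region shaded. The mother and progeny 3, 5, 6 and 7 rise together over the region to a mean of 0.55, and the father and progeny 1, 2 and 4 stay near 0.

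The shorter segregating regions were mostly gains carried by few mice. In all there were 240 segregating regions, 183 gains and 57 losses, of which 229 spanned 3 to 4 probes, and the track without copy number gave 79. With the mouse in Cy3 only the split was 78 gains and 69 losses. In their own calls the father had 55 gains and 16 losses and the mother 106 and 26. Losses outnumbered gains in each progeny mouse, with 57 gains and 59 losses in progeny 7 and 53 and 190 in progeny 3. The parents were scanned on a day of their own, so an effect of the arrays or the day on this split cannot be told apart from inheritance. A loss of 3 probes on chromosome 3 from 25417435 to 25432738 was the deepest of the named ones, at -1.58 ± 0.35 (SE over 3 probes) in the mother and -1.60 ± 0.36 in progeny 7, against -0.16 to 0.12 in the other 7 mice. It held without its strongest probe, at -1.23 and -1.24. A loss of 1 of 2 copies corresponds to -1 on this scale, and the means lay below that. This pair of mice was also the only one with Y chromosome medians far below the reference, at -2.29 and -2.53, so the loss cannot be read as an inherited deletion from these values. Losses in the same pair of mice on chromosome 6 from 104236953, chromosome 3 from 132546474, chromosome 5 from 123592752, chromosome 11 from 112957750 and chromosome 9 from 35857910 had means of -0.86, -0.82, -0.78, -0.62 and -0.75 in the mother, and the probes other than the strongest averaged between -0.13 and 0.11 there. The remaining named regions were a loss in the mother on chromosome 5 from 21621449 (-0.74) and gains on chromosome 14 from 69820208 (0.88 in the mother) and on chromosome 17 from 18555786 (0.71 in the mother). Of the 10 named segregating regions, 3 kept a mean of at least 0.25 in size without the strongest probe in every mouse that called them.

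Most pairs of a region carried by 1 parent and a progeny mouse were without the region. Over 197 such regions, 172 of 1379 pairs of region and progeny mouse were carriers, 12.5%, and 91 regions were found in 0 progeny. The same measure on the track without copy number was 8.76% over 75 regions. The permutation test over regions against 50% gave p = 1e-05, the smallest it can give, on both tracks, so it says nothing about inheritance. Among the 11 regions of at least 5 probes the share was 27.3%, 21 of 77 pairs.

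A progeny-only region of at least 10 probes was seen 2 times, and each was a shallow loss in the called mouse. The first lay on chromosome 3 from 53037171 to 53057498 (10 probes), at -0.38 ± 0.15 (SE over probes) in progeny 2 against 0.08 ± 0.03 (SD, n = 8) in the other mice, and without its strongest probe it was -0.27. The second lay on chromosome 10 from 113383359 to 113413795 (12 probes), at -0.26 ± 0.05 in progeny 1 and -0.18 ± 0.06 in progeny 6. The other 7 mice had 0.04 ± 0.12 (SD, n = 7) there and ranged from -0.11 to 0.27. The track without copy number also gave 2 progeny-only regions of this length. Neither was called at this length with normexp, with the deposited value table or at a score of 8, and progeny 2 had the noisy array.

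In all there were 510 progeny-only regions, 153 gains and 357 losses, of which 477 spanned 3 to 4 probes and 387 were carried by 1 mouse. The track without copy number gave 324. Losses were nearly matched by gains with the mouse in Cy5 only, at 154 gains and 177 losses, and with normexp, at 8 and 9. Progeny 3, with the dimmest arrays, carried 265 of them and progeny 2 carried 10. The count was 17 with normexp, 174 without dim or marked spots and 280 without progeny 3, against 233 on the track without copy number.

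The 10 strongest progeny-only regions all spanned 3 probes, and 2 of them held without their strongest probe. These 2 were a gain on chromosome 4 from 84509920 to 84515749 in progeny 7 (0.98 ± 0.51, SE over 3 probes, and 0.55 without the strongest probe) and a gain on chromosome 5 from 47414515 to 47421447 in progeny 3 (1.07 ± 0.75 and 0.33). The region of largest score, a loss on chromosome 3 from 10344576 in progeny 4, had a mean of -1.16, which came from 1 probe at -3.34 while the other 2 averaged -0.08. The remaining ones were gains on chromosome 7 from 104177758 and chromosome 15 from 77370705 in progeny 7, on chromosome 2 from 5886738 in progeny 1 and on chromosome 9 from 102202268 in progeny 5, and losses on chromosome 4 from 66287836 and chromosome 10 from 61845870 in progeny 7 and on chromosome 1 from 47145257 in progeny 4 and 7. Their probes other than the strongest averaged between -0.19 and 0.19. As a description of these DNA samples, the difference between the mean of 7 progeny and the mean of 2 parents placed 109 of the 510 regions in the outer 1% of 10000 random windows, against 5.1 by chance, but the regions were chosen for deviating in progeny.

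Directly compared, the difference between father and mother with the largest score, which weighs size by probe number, was the chromosome 4 gain, where the father was lower by a log2 difference of -0.56. The only other difference of at least 10 probes lay on chromosome 14 from 113782810 to 113808467 (12 probes), where the father was higher by 0.32, with 0.27 ± 0.11 (SE over probes) in the father and -0.05 ± 0.03 in the mother. The next in score were the loss of the mother on chromosome 3 from 25417435 (difference 1.68), a lower value of the father on chromosome 14 from 53961688 to 53969126 (-1.13) inside the shared loss, and a higher value of the father on chromosome 2 from 70082725 (0.48 against -0.53 in the mother). The losses of the mother on chromosome 6 from 104236953 and chromosome 3 from 132546474 followed (0.94 and 0.88). The last 4 of the named differences, on chromosome 3 from 135378985, chromosome 10 from 34109364, chromosome 9 from 90435221 and chromosome 15 from 48295378, were -0.84, -0.82, -0.81 and 0.80. The search gave 63 differences, 22 higher and 41 lower in the father, with the order reversed to 11 and 5 by normexp, but 101 on the track without copy number, so the count of short differences as a whole did not exceed the background. With 1 animal on each side there was no test across animals.

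Autosomal medians lay between -0.0078 and 0.0064 in all 9 mice, and 0 of 19 passed the threshold over the 7 progeny (exact sign-flip permutation test, smallest adjusted p = 0.297). That is also the smallest adjusted p that 1 autosome alone can reach with 7 progeny, so the test could not call a single chromosome. Unadjusted, 2 had a p under 0.05: chromosome 16 with a mean of 0.0038, above 0 in 7 of 7 progeny (exact permutation p = 0.0156, the smallest possible), and chromosome 18 with a mean of 0.0022, above 0 in 6 of 7 (exact permutation p = 0.0312). The count was 18 with normexp, 6 with the mouse in Cy5 and 14 with the mouse in Cy3, with means no farther from 0 than 0.0093. On the few sex chromosome probes, the median log2 ratio on X was 0.92 in the mother and 0.94 in progeny 7 and between -0.03 and 0.06 in the other mice, and on Y it was -2.29 and -2.53 against -0.08 to 0.04. Progeny 7 thus had the same sex chromosome ratios as the mother relative to the male reference.

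At single probes the family was more often below than above the reference, and no probe passed the test between progeny and parents. With limma, 3519 of 950617 probes passed the threshold for the family against the reference, 354 higher and 3165 lower. They included all 19 probes of the loss on chromosome 10 and 54 of the 79 of the loss on chromosome 14, but 3412 stood alone with no neighbour past the threshold in the same direction. Of those below the reference, the smallest p belonged to A_67_P07024020 (-0.64 ± 0.03, SE) and A_67_P02099779 (-0.63 ± 0.03) on chromosome 10, each with an adjusted p of 9.89e-06 from limma and between -0.78 and -0.50 in all 9 mice. Among those above the reference were A_67_P07712575 on chromosome 12 at 95868420 (0.81 ± 0.06, adjusted p = 4.57e-05) and A_67_P02139160 on chromosome 10 at 61623347 (0.59 ± 0.05, adjusted p = 0.000135). The count was 0 with trend and robust variance in limma, 1906 with normexp and between 1139 and 5627 with single progeny left out.

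Between progeny and parents, 0 of 950617 probes passed the threshold in limma, with 29696 at an unadjusted p under 0.05 and a smallest adjusted p of 0.996. With scan day as a random block the count was also 0, with 36124 unadjusted. The parents were scanned together on a day of their own. In the simulation of this comparison 83.5% of changes of 1 on the log2 scale were recovered but 0% of changes of 0.5, so a change of that size at a single probe was not detectable.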

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

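Of the tests in this part, the test of independent inheritance was chosen only after the result was seen. Of 64 sets of values compared over the 7 progeny, 17 had 1 mouse standing apart from the others, where chance gives about 1 in 20, and regions called in 1 progeny mouse stand apart by construction.

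On the sex chromosomes, progeny 7 stood apart with a median of 0.94 on X and -2.53 on Y, while the other 6 progeny lay between -0.03 and 0.06 on X and between -0.08 and 0.04 on Y. The mother, outside the progeny, had 0.92 on X and -2.29 on Y. These probes were not part of the interval search.

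The array with progeny 2 in Cy5 had an SD of ratios between neighbouring probes of 0.431, against 0.205 to 0.254 in the other progeny in that dye. The median of chromosome 3 was -0.0042 in progeny 6 and between 0.000437 and 0.0029 in the others.

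Progeny 7 was also far from the other progeny in several 3-probe regions where the mother was low too: -1.60 on chromosome 3 from 25417435, -0.76 on chromosome 6 from 104236953, -0.58 on chromosome 5 from 123592752, -0.85 on chromosome 11 from 112957750 and -0.68 on chromosome 9 from 35857910. Of the 18 losses carried by the mother and exactly 1 progeny mouse, 17 were carried by progeny 7, on 10 chromosomes, and of the 28 gains so carried progeny 7 had 8, against at most 4 in any other progeny mouse. Unlinked maternal deletions passed on independently would reach progeny 7 in about 1 in 7 cases, which the test argues against (exact binomial p = 6.69e-14). Another candidate explanation is autosomal probes that also bind Y chromosome DNA, which the male reference has and these 2 mice do not show. Of the mother's 63 low probes (log2 ratio under -0.7, and low in both dye orientations), 23 were low in progeny 7. That was 2.09 times the 11 in the next mouse, the father, and between the limits of 3 and 1.5 set for and against it. The median ratio over the 63 probes was -0.60 in progeny 7 and between -0.25 and -0.06 in the father and the other progeny. This explanation predicts such a gap, but any sharing of losses with the mother predicts it too. The explanation thus stays open for the losses. Binding to Y DNA alone does not predict gains, but an excess of gains in progeny 7 was not tested. Of the mother's high probes (the same limits with the sign reversed), 15 were high in progeny 7, 17 in progeny 5 and 88 in the father. In the other progeny 5 to 11 were, so sharing of high probes with the mother was not particular to progeny 7. The shared low probes were also bright in the reference, at a median log2 signal of 2.04 above the array median, which a probe with several targets would be too, and a biological difference was not tested apart from inheritance.

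In progeny 7, 3 further regions stood apart: 0.98 on chromosome 4 from 84509920, 0.86 on chromosome 7 from 104177758 and -0.78 on chromosome 4 from 66287836. Progeny 3 stood apart at 1.07 on chromosome 5 from 47414515 and at -0.57 on chromosome 11 from 76354520, a region called as a gain in progeny 1, 5 and 7. Progeny 1 was at 1.02 on chromosome 2 from 5886738, progeny 5 at 0.82 on chromosome 9 from 102202268 and progeny 2 at -0.38 on chromosome 3 from 53037171.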

How the results depend on the processing

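The alternatives that keep calls of at least 10 probes, that drop calls resting on their strongest probe or that apply the size rule inside the search were chosen after seeing the data. Counts are given in the order calls, segregating, progeny-only and father against mother, against 808, 240, 510 and 63. They were 2049, 630, 1315 and 174 at a score of 5 and 149, 40, 81 and 12 at a score of 8. They were 261, 68, 165 and 24 with at least 5 probes, 161, 112, 17 and 16 with normexp, and 335, 125, 174 and 21 without dim or marked spots. They were 20, 1, 2 and 2 for calls of at least 10 probes and 322, 94, 201 and 22 for calls that held without their strongest probe, where the tracks without copy number gave 103 progeny-only regions. With a mean ratio limit of 0.4 the first 3 counts were 354, 96 and 230. With the mouse in Cy5 there were 331 progeny-only and 205 father against mother regions, and in Cy3 147 segregating and 128 father against mother regions. The shared losses fell from 2 to 1 with a limit of 0.4, with normexp and with the stricter carrier share. Longer or stricter limits leave fewer calls by construction, and for the other changes the cause was not tested.

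Normexp also moved the split of gains to losses, from 359 and 449 to 90 and 71 for calls, from 183 and 57 to 72 and 40 for segregating, from 153 and 357 to 8 and 9 for progeny-only and from 22 and 41 to 11 and 5 for father against mother regions. Gains and losses among calls were 412 and 272 in Cy5 and 306 and 259 without progeny 3. Progeny-only regions numbered 280 to 507 with 1 progeny mouse left out, the lowest without progeny 3. The family probes past limma's threshold were 0 with trend and robust variance, 1906 with normexp, 4361 with scan day as a random block and 1139 to 5627 with 1 progeny mouse left out: 1300 without progeny 1, 5627 without progeny 2, 1921 without progeny 3, 2088 without progeny 4, 1139 without progeny 5, 1482 without progeny 6 and 5020 without progeny 7. Progeny against parents gave 0 to 1, the 1 without progeny 6. Chromosome medians past the threshold were 18 with normexp, 6 in Cy5 and 14 in Cy3.

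The chromosome 4 gain was called in the same number of mice, 5, in all 11 alternatives compared for long regions, and its mean ratio stayed between 0.47 and 0.57. The chromosome 10 loss was called in 9 mice, except for 8 in Cy5, at -0.56 to -0.52, and the chromosome 14 loss in 0 to 8 mice, at -0.31 to -0.23. Signal over background was lowest in progeny 3. A scan day block for the interval counts and the gene lists were not run. No paired analysis between groups was possible because all progeny share the same father and mother, which gives no matched pairs of animals.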

Other observations

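Of the tests in this part, those of a single copy number step, of array noise, of dim arrays and of dim or marked spots were chosen only after the result was seen.

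Some 3-probe regions were called in at least 3 mice, and none of these 5 kept a mean of at least 0.25 in size without its strongest probe in every mouse that called it. A gain on chromosome 4 from 30870820 to 30877356 had means of 0.75 in progeny 2, 0.68 in progeny 4, 0.62 in progeny 1 and 0.49 in the mother, and of 0.07 in progeny 7, with the other 2 probes at 0.17 in progeny 1. A gain on chromosome 11 from 76354520 to 76359325 was at 0.68 in progeny 7, 0.58 in progeny 5 and 0.44 in progeny 1, with 0.46 in the father, but in progeny 5 the other 2 probes averaged 0.03. On chromosome 13 from 95703166, the father (0.66), progeny 5 (0.52) and progeny 7 (0.39) were high through 1 probe, as the other 2 probes averaged between -0.05 and 0.04. Gains on chromosome 2 from 70084179 and losses on chromosome 7 from 7068073 were called in the father and 2 progeny mice, with the other 2 probes at -0.18 for the first in progeny 4 and at 0.14 and -0.10 for the second in progeny 3 and 7.

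The uneven loss on chromosome 14 was compared with what a single difference of the reference mouse would give. A single step with fixed ends predicts the same ratio along the region, and the spread between 100 kb bins exceeded that of shuffled probes (permutation p = 0.0002). Probes that match several genomic copies would be bright. The median reference signal of the region's 79 probes lay at the 99.9 percentile of random windows of as many probes. Brightness also depends on probe sequence, and an extra copy in the reference mouse would raise it too. It was 0.70 here, 0.66 over the even loss on chromosome 10 and 0.03 over the chromosome 4 gain (median log2 signal above the array median). An extra copy in the reference alone would raise its signal only by the size of the ratio. The mean ratio was -0.29 here and -0.56 on chromosome 10. The brightness of 0.70 on chromosome 14 exceeded that size, which argues against an extra copy in the reference as its only source. For the rest, the test cannot tell probes that match several genomic copies from an effect of probe sequence. A chromosome 14 difference made of several steps stays open. Biological explanations that depend on the genes in the region were not tested, because no annotation of this build was used here.

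The excess of progeny-only regions, 510 against 324 on the tracks without copy number, was weighed against noise. Array noise cannot be told apart from other causes: each progeny mouse carried more regions on the real track (exact sign-flip permutation p = 0.0156, the smallest possible), but mice can carry regions called in others, by their own calls 4 of 7 had more (exact permutation p = 0.25), and without progeny 3 there were 280 against 233, 1.2 times as many. Leaving out positions dim or marked on any array removed 1.4% of autosomal positions. Without them 174 against 49 regions were left, 3.55 times as many, and 2.37 times without progeny 3. This argues against those positions as the whole cause. Weak spots above the limit stayed in. With normexp 17 regions were left, and no track without copy number was made for it, so weak spots in general stay open as a cause. The number carried fell with the median signal of the mouse's channel (Spearman's rho = -0.86, permutation p = 0.0238, and Pearson's r = -0.86, permutation p = 0.0107, n = 7), and r was -0.84 without the 2 mice farthest from the median signal, so DNA or labelling quality of single samples may contribute. Of the 3 scan days with 2 progeny, the mouse with the higher signal carried fewer regions on 2 (10 against 52 and 140 against 265). On the other day it carried more (53 against 49). By its own calls, however, it had fewer on each of the 3 days (3 against 36, 119 against 234 and 14 against 25). New aberrations in progeny stay untested.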
